A study of Mus musculus with 3 samples.

How the data were processed

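RNA was measured by sequencing in 3 mouse cultures, 1 library each. The cultures were grown from mouse embryonic stem cell lines named WT (wild type), BM (Barhl1 mutant) and BEM (mutant in an E-box site, a short motif bound by basic helix-loop-helix transcription factors, named E3 in the labels). Otic progenitors, the precursors of inner ear cells, were grown to culture day 9 on mitotically inactivated stromal cells of the embryonic chicken utricle, with EGF at 25 ng/ml and retinoic acid at 1 µM, per the labels' protocols. Messenger RNA was enriched with oligo-dT and libraries were made with the TruSeq kit, per the labels' protocols. Whether reads from the chicken cells were set apart is not given in the sources used here.

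The files were 3 tables, 1 for each pair of libraries, with 47725 genes in each; 4 further lines of each table were not analysed here. The deposited expression values were FPKM (reads scaled by gene length and by the library's total), per the file headers. The deposited tables also held the authors' log2 ratio for each pair, per the file headers. The authors' p-value and FDR for each gene stood beside it in the deposited tables, per the file headers. TopHat2, HTSeq, edgeR and the mouse build GRCm38 are named in the submitters' processing notes, with no versions. How a p-value was reached from 1 library per line is not given in the sources used here, so these values are given only as the authors' own. Gene positions came from the GENCODE annotation of GRCm38, in which 47220 of the 47725 gene identifiers were found. For 10788 genes the symbol came from that annotation alone.

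The tables held no counts, so the intended ratio of scaled counts was replaced by the fallback fixed for that case, log2 of the deposited FPKM plus a pseudocount of 0.5, with no further scaling. The filter on low values, written for CPM, was applied to FPKM as well: genes with a mean of at least 1 FPKM over the 3 libraries were measured, which left 12875 genes. Genes 2-fold apart on that scale were counted in each direction. The pseudocount pulls the ratio of low genes towards 1. Folds given for single genes are ratios of the deposited FPKM without the pseudocount.

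FPKM are whole reads divided by gene length and library total, so the reads behind each gene were recovered by finding the length and total that made all 3 values whole to within 0.0001 reads. The totals were 21555823 reads for WT, 20111794 for BM and 23813123 for BEM. Whole reads were recovered for 12873 of the 12875 measured genes, and for 72.1% of those at the length the annotation gives. For the other genes the length is a choice among several that work, so their reads are less certain. As a check, each value of 1000 measured genes was shifted slightly at random, and 4 of these genes then gave whole reads. Recovered reads were used for 95% intervals of the ratio of 2 libraries (exact, Clopper-Pearson) and for comparisons with counting noise. Intervals and floors cover counting error only, since reads of PCR-amplified libraries without molecular identifiers are not independent molecules. A fold against 0 reads was computed against a floor of 3 reads in that library and is given as a lower bound, which lies somewhat above the lower end of the 2-sided 95% interval for the same reads.

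With 1 library per line there is no replicate check of any difference, no p-value across genes was computed, and a comparison of reads compares these libraries and not the conditions. The comparisons were BM with WT, BEM with WT and BEM with BM, followed by the overlap of the first pair. The median log2 ratio of each of 28 gene lists was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The lists, the comparisons and the rule for named genes were chosen before the data were examined. The rule took Barhl1, Barhl2 and the genes beside Barhl1 and, per comparison, the 8 genes with the largest ratio in each direction among those of at least 5 FPKM in the higher library. Predicted or clone symbols and the sex-linked, mitochondrial and ribosomal lists were left out of that part. It also took up to 4 members of each list with the largest ratio, at least 20 reads in 1 library and a counting interval that excluded 1, as well as Atoh1, Pou4f3, Gfi1, Myo7a, Espn and Otof. The last part took the 6 genes in each direction with the largest difference from WT shared by BM and BEM. Other settings, also fixed beforehand, were median-of-ratios and upper quartile scaling, no filter or a mean of 10 FPKM, a pseudocount of 5, a 4-fold threshold, a threshold on the counting interval and the authors' ratios. TMM scaling, a pseudocount of 0.05 and leaving out the genes without whole reads were chosen after seeing the data.

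The procedure was tested on simulated data made from the expressed genes, 26463 in number. For BM against WT the library total was recovered with an error of 0 reads, and reads came back for 100% of 500 genes given their right length. Given a wrong length, reads came back for 93.0% of 300 genes with at least 100 reads and for 60.0% of 300 genes with fewer. The other 40.0% of the latter were given more reads than they had, which makes their counting intervals too narrow. Of counting intervals made from the true simulated reads and totals, 97.1% held the true ratio. Exact intervals of such counts hold it at least 95% of the time by construction, and intervals from recovered reads were not tested. Of 50 genes changed by -2 on the log2 scale, 98.0% were counted in the right direction, and 100% of 50 genes changed by 2. Of 12650 unchanged genes, drawn with counting noise alone, 82 were counted as 2-fold apart. With no spread between libraries simulated, this does not give the rate between separate cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.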

Results

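Gene expression was profiled in cultures grown from WT, BM and BEM mouse embryonic stem cells, with 1 library per line. The series asks how mutations at the locus of Barhl1, a homeobox transcription factor gene expressed in inner ear hair cells, alter the transcriptome of these cultures. The recovered reads in genes came to 21350126 in WT, 19957807 in BM and 23628500 in BEM. Genes of at least 1 FPKM numbered 13086 in WT, 12204 in BM and 12237 in BEM. Each line had 1 library, so no difference here has a replicate check, and the 95% intervals given for ratios cover counting error only.

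Barhl1 (ENSMUSG00000026805), on the minus strand of chromosome 2 from 28907679 to 28916668 in GRCm38, stood at 126.5 FPKM in WT, 95.1 FPKM in BM and 0.0107 FPKM in BEM. The Barhl1 level was thus 1.33-fold lower in BM than in WT, and close to 0 in BEM. The kind of mutation in BM is not given in the sources used here, so its transcript level does not check that label. The Barhl1 values did not correspond to whole reads and carry no counting interval. Its relative Barhl2 had 3 reads in WT and 0 in both mutants. Of the genes beside Barhl1, Ddx31 was 1.95-fold higher in BM than in WT (1.62 to 2.36), at 2.38 FPKM in WT, 4.64 in BM and 4.37 in BEM. Gtf3c4, at 10.2, 10.1 and 9.86 FPKM in WT, BM and BEM, and Ttf1, at 4.63, 4.73 and 5.01 FPKM, lay close together in the 3 libraries. Ak8 and Cfap77 stayed below 0.3 FPKM in each library.

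**Figure D1:**
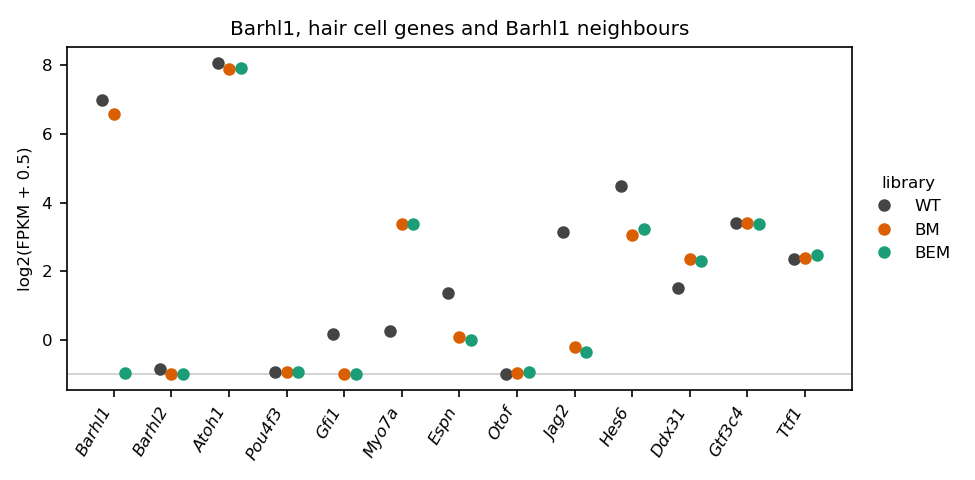
Expression of Barhl1, Barhl2, hair cell genes and Barhl1 neighbours in the WT, BM and BEM libraries, as log2(FPKM + 0.5) on the vertical axis, with 1 point per gene and library and a grey line at 0 FPKM. Barhl1 lies near the grey line in BEM only, at 0.0107 FPKM, while Atoh1 lies between 236.5 and 270.2 FPKM in the 3 libraries.

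The comparison of BM with WT asks what differs in the Barhl1 mutant culture. Lyz2, C1qa and Acta2 were higher and Ecel1 and Stra6 lower in BM than in WT. Lyz2, which encodes lysozyme, stood at 3.08 FPKM in WT and 1380 FPKM in BM, 448-fold higher (332 to 622). C1qa, a subunit of complement C1q, had 0 reads in WT and 2501 in BM, at least 894-fold higher. Acta2, smooth muscle actin, was 69.6-fold higher in BM (66.1 to 73.4), from 37.0 to 2576 FPKM. Genes lower in BM included Ecel1, a metalloprotease of neurons, at 123.3 FPKM in WT and 0.0568 FPKM in BM, 2170-fold lower (847 to 7967), and Stra6, the retinol transporter, 382-fold lower (247 to 626).

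In all, 1356 genes were at least 2-fold higher and 1970 at least 2-fold lower in BM, which is 25.8% of the 12875 measured genes. The counting interval excluded a ratio of 1 for 1324 and 1909 of them. With predicted and clone symbols left out, other genes near the top were Gpnmb, a glycoprotein of macrophages and osteoclasts, 360-fold higher (284 to 464), and Actg2, enteric smooth muscle actin, with 3 reads in WT and 2765 in BM, a ratio of 988 (338 to 4793). The microglial and macrophage signalling adaptor Tyrobp, the lysosomal protease Ctss and the complement gene C1qb each had 1 read in WT and 1080, 2238 and 1375 reads in BM. The processed pseudogene Rps2-ps10, which can share reads with its parent gene, was 230-fold higher (158 to 349). At the other end, Scg2, a secretogranin of neuroendocrine granules, was 289-fold lower (181 to 497), Fmo2 was 455-fold lower (254 to 912), and Rtn4rl2 was 236-fold lower (108 to 643). Saa3 and C3, which belong to the acute-phase and complement response, were 186-fold (97.8 to 407) and 118-fold lower (98.7 to 142), and G0s2, an inhibitor of lipolysis, was 162-fold lower (82.0 to 376).

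Most hair cell genes were too low to be measured. A mean of at least 1 FPKM was reached by 3 of 13 early hair cell genes, 9 of 34 hair bundle genes and 5 of 21 synapse and channel genes. Hair cell genes that differed from WT went in both directions. Atoh1, the transcription factor that starts hair cell differentiation, stood at 270.2 FPKM in WT and 236.5 in BM, in values that were not whole reads. Of the other early hair cell genes, Hes6 was 2.79-fold lower (2.43 to 3.2), the Notch ligand Jag2 22.4-fold lower (13.4 to 40.5), and Gfi1, with 43 reads in WT and 0 in BM, at least 13.4-fold lower. Pou4f3, needed for hair cell survival, had 1 read in each library, and Otof, the calcium sensor of the hair cell synapse, had 0 reads in WT and 2 in BM. Of the 9 measured genes of the hair bundle, 2 were at least 2-fold higher and 3 at least 2-fold lower. Myo7a, an unconventional myosin of stereocilia, was 13.9-fold higher (11.6 to 16.8), while the bundle scaffold Whrn was 5.19-fold lower (4.60 to 5.88) and Triobp 2.20-fold lower (2.08 to 2.33). The actin bundler Espn, at 2.08 FPKM in WT and 0.565 in BM, was 3.67-fold lower (2.92 to 4.66). Clic5, with a mean under 1 FPKM and so not counted, was 9.69-fold lower (5.48 to 18.7). The list's median log2 ratio was -0.11 and became 0.035 with upper quartile scaling. Of 5 measured synapse and channel genes, 1 was higher and 2 lower, with Bdnf 3.91-fold higher (3.19 to 4.82) and Rims2 110-fold lower (42.8 to 407).

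Supporting cell and Notch genes split, with 5 of 14 higher and 4 lower. Jag1 was 13.4-fold higher (12.1 to 14.8), Lgr5, with 7 reads in WT, was 187-fold higher (90.4 to 466), and Sparcl1 was 51.3-fold lower (46.0 to 57.4). Of 9 otic progenitor genes, 5 were lower, among them Tbx2 (9.90-fold, 8.32 to 11.9), Six4 (6.12-fold, 5.11 to 7.37) and Gata3 (5.84-fold, 4.42 to 7.84), and 2 were higher, among them Eya4 (4.02-fold, 3.2 to 5.11).

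Genes that respond to retinoic acid, a component of the culture medium, were lower for 9 of the 12 measured, with a median log2 ratio of -2.48 that lay below each of 10000 random lists. Rarb, a retinoic acid receptor, was 42.6-fold lower (30.8 to 60.7) and Cyp26b1, which degrades retinoic acid, 23.9-fold lower (21.8 to 26.2). The binding protein Crabp1 went the other way, at 13.4 FPKM in WT and 537 in BM, 40.2-fold higher (35.3 to 46.0). Of 14 targets of Wnt, Hedgehog, BMP and FGF signalling, 11 were lower and 1 higher, with a median of -1.84. Spry4 (11.4-fold, 10.2 to 12.7), Etv4 (6.38-fold, 5.70 to 7.17) and Dusp6 (5.97-fold, 5.50 to 6.48), which respond to FGF, and the Wnt factor Tcf7 (19-fold, 12.2 to 31.0) were lower, and Id2 was 3.2-fold higher (2.73 to 3.77). Of 16 hypoxia and glycolysis genes, 9 were lower and 1 higher, with a median of -1.28; Egln3 was 32.2-fold lower (26.1 to 40.03) and Hk2 8.46-fold lower (7.88 to 9.09), while Eno1 was 2.19-fold higher (2.13 to 2.25). Immediate early and stress genes were lower for 7 of 10, with a median of -1.39, including Hspa1b (13.0-fold, 12.3 to 13.7) and Egr1 (4.40-fold, 4.16 to 4.66).

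Mesenchymal and proliferation genes were higher. Of 19 mesenchyme and fibroblast genes, 11 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.56 above each of the random lists. Tagln was 38.1-fold higher (35.6 to 40.7), Bgn 17.1-fold (16.6 to 17.6), Thy1 15.5-fold (14.3 to 16.7) and the collagen gene Col1a1 2.62-fold (2.61 to 2.64). Of 22 proliferation genes, 13 were higher and 0 lower, with a median of 1.24, also above each random list. The mitotic genes Cenpe, Plk1, Ccnb1 and Ccnb2 were 5.64-fold (4.90 to 6.51), 5.21-fold (4.41 to 6.19), 4.72-fold (4.12 to 5.43) and 4.56-fold higher (3.84 to 5.45).

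Markers of other cell types went both ways. The 4 measured endoderm and liver genes were all lower, with a median of -3.75, including Foxa1 with 863 reads in WT and 2 in BM (403-fold, 111 to 3330). Their median was -0.181 over all 15 genes of the list, most of them of low expression, and -1.35 with a pseudocount of 5. Epithelial genes were lower for 3 of 4, with Cldn4 12.9-fold lower (7.88 to 22.5) and Krt18 7.24-fold lower (5.90 to 8.94). Neural progenitor and glial genes were lower for 2 of 4, with Msi1 12.3-fold lower (9.70 to 15.8) and Nes 3.15-fold lower (2.99 to 3.31). Neural crest genes were lower for 2 of 3 and included Tfap2a, 4.86-fold lower (3.25 to 7.50), but their median of -1.01 changed sign to 0.567 when genes of low expression were included. Of 5 neuronal genes 3 were higher, such as Gap43 (32.1-fold, 22.0 to 48.6) and Tubb3 (10.4-fold, 7.13 to 15.7), and 1 was lower, Nefm (70.9-fold, 39.4 to 143). Their median was 1.53 and changed sign to -0.156 when genes of low expression were included. The endothelium and blood list had 3 of 5 higher, Lyz2, Ptprc and Csf1r, which also stand among the macrophage genes examined below. Csf1r had 2 reads in WT and 1484 in BM, a ratio of 795 (220 to 6573). The 1 lower gene was the endothelial gene Egfl7, 4.60-fold lower (3.30 to 6.54). Tie1, also endothelial and with a mean under 1 FPKM, had 85 reads in WT and 0 in BM, at least 26.4-fold lower. Of 3 cardiac and skeletal muscle genes 2 were higher, with Acta1 at 2 reads in WT and 520 in BM, a ratio of 279 (76.8 to 2307). Their median of 1.16 also changed sign, to -0.054, with genes of low expression included. The pluripotency and motile cilia lists had 2 and 1 measured genes. Klf4 was 3.01-fold higher (2.72 to 3.34), Klf2 1.86-fold lower (1.60 to 2.17) and Cfap43 1.34-fold higher (1.26 to 1.43). The members of these lists named with a mean under 1 FPKM were lower. Foxj1 of the cilia list, with 93 reads in WT and 3 in BM, was 28.9-fold lower (9.6 to 143). Dnaic2 was 2.80-fold (2.045 to 3.88), Ccdc40 2.80-fold (1.74 to 4.65) and Nanog of the pluripotency list 2.80-fold lower (1.22 to 7.21).

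Among 14 imprinted genes 7 were lower and 1 higher, with a median of -1.02. Dlk1 stood at 791 FPKM in WT and 44.5 in BM, 17.8-fold lower (17.3 to 18.3), Mest was 18.5-fold lower (17.1 to 20.01) and Peg10 13.6-fold lower (12.3 to 15.03). Grb10 went from 0.475 FPKM in WT to 98.2 in BM, 207-fold higher (169 to 256). Of 25 Hox genes 12 were lower and 6 higher; Hoxa3 was 10.7-fold (8.56 to 13.7) and Hoxa5 9.41-fold lower (7.85 to 11.4), while Hoxc10 was 16.6-fold (11.5 to 24.7) and Hoxa10 48.7-fold higher (23.4 to 122). The Hox median of -0.79 became 0.015 with genes of low expression included. Reference groups lay closer to 0, with a median of 0.068 for 75 ribosomal protein genes, -0.051 for 14 p53 targets, -0.18 for 25 mitochondrial transcripts and 0.38 for 13 housekeeping genes, 4 of which were at least 2-fold higher, B2m the most (3.85-fold, 3.74 to 3.97). Upper quartile scaling would move BM to WT log2 ratios up by at most 0.173, less for low genes because of the pseudocount, and the p53 median became 0.116 with it. Of the genes 2-fold apart 40.8% were higher in BM, and 48.3% of those with a mean of at least 10 FPKM. The authors' deposited table marked 1554 genes as significant for BM against WT, 592 higher and 962 lower, and gave Barhl1 a log2 ratio of -0.41 and an FDR of 1.0.

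**Figure D2:**
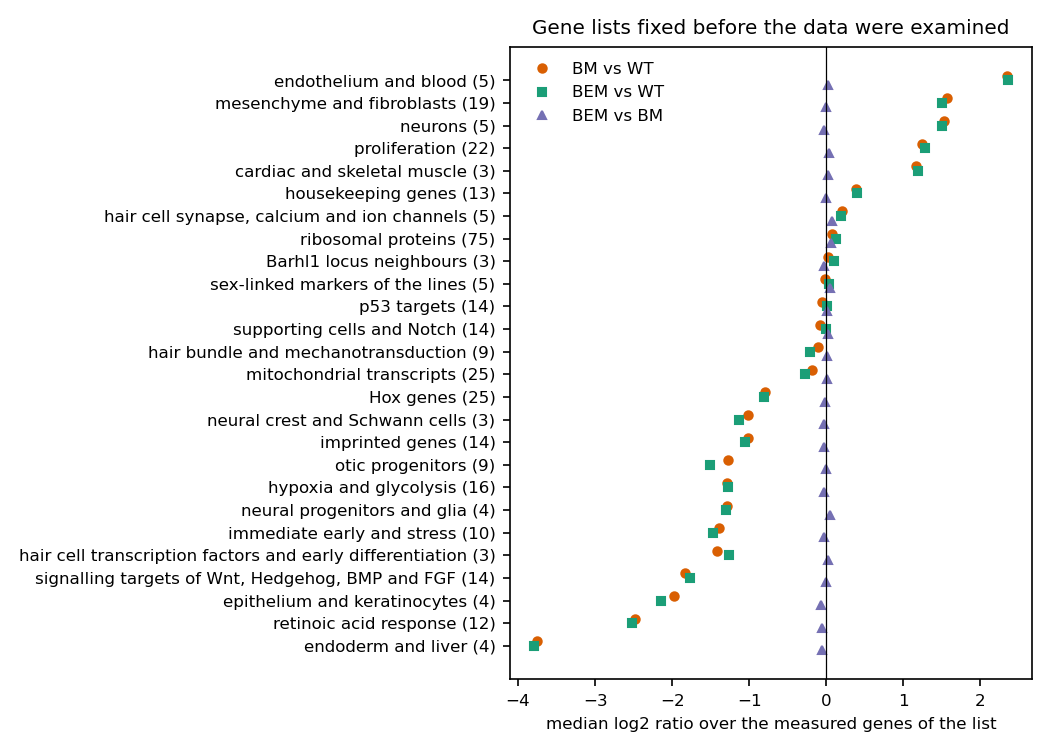
Median log2 ratio, on the log2(FPKM + 0.5) scale, of each gene list with at least 3 measured genes (number in brackets), for BM against WT (circles), BEM against WT (squares) and BEM against BM (triangles). Circles and squares lie close together for each list, from -3.75 and -3.79 for endoderm and liver to 2.34 and 2.36 for endothelium and blood, while triangles lie within 0.07 of 0. In the endothelium and blood list the endothelial gene Egfl7 was lower in both mutants than in WT.

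The comparison of BEM with WT asks what differs when the E-box site is mutated. Barhl1 had a log2 ratio of -7.96 on the log2(FPKM + 0.5) scale and was among the lowest genes in BEM relative to WT. Genes higher in BEM included those named for BM: Lyz2 at 1409 FPKM was 458-fold higher than in WT (339 to 635), C1qa at least 948-fold higher, and Acta2 at 2578 FPKM 69.7-fold higher. Among genes lower in BEM were Rtn4rl2, with 2 reads in BEM and 1515 in WT, 837-fold lower (231 to 6916), Ecel1, 643-fold lower, Saa3, 496-fold lower (193 to 1820), Stra6, 431-fold lower, and the secreted lectin Chil1, 374-fold lower (190 to 868).

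In BEM 1372 genes were at least 2-fold higher and 1967 at least 2-fold lower than in WT, which is 25.9% of those measured, and the counting interval excluded 1 for 1336 and 1912. Hair cell genes lay near their BM levels, with Atoh1 at 240.9 FPKM, Myo7a at 9.83 FPKM (14-fold higher than in WT), Espn at 0.503 FPKM (4.13-fold lower), Hes6 at 8.87 FPKM (2.48-fold lower), Jag2 at 0.290 FPKM (28.5-fold lower) and Gfi1 at 0 reads (at least 15.8-fold lower). Otof had 4 reads. Sox2, a factor of supporting cells and progenitors, was 25.8-fold lower, with 187 reads in WT and 8 in BEM. Retinoic acid genes had 9 of 12 lower with a median log2 ratio of -2.52, signalling targets 11 of 14 lower (-1.77), hypoxia genes 9 of 16 lower (-1.27), and immediate early genes 7 of 10 lower (-1.47). The 4 measured endoderm and liver genes had a median of -3.79, or -6.63 with the 3 genes at 0 reads in BEM at their bound, against -0.106 over all 15 genes of the list and -1.35 with a pseudocount of 5. Fgb was at least 474-fold and Foxa1 at least 318-fold lower. Mesenchyme genes had 11 of 19 higher (1.495) and proliferation genes 13 of 22 higher (1.28). Imprinted genes (-1.06, 7 of 14 lower), Hox genes (-0.81, 12 lower and 6 higher of 25) and otic progenitor genes (-1.504, 5 of 9 lower) also had the split seen in BM. With upper quartile scaling BEM to WT log2 ratios would move up by at most 0.168. The authors' deposited table marked 1643 genes as significant for BEM against WT, 636 higher and 1007 lower, and gave Barhl1 a log2 ratio of -13.52.

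BM and BEM shared most of their differences from WT. Of the genes at least 2-fold higher, 1279 were the same in both, against 144.5 for independent lists of those sizes, and of those lower 1826, against 301.0. With predicted and clone symbols left out, the shared genes with the largest differences were Lyz2, C1qa, Gpnmb, Rps2-ps10, Ctss and Actg2 on the higher side and Ecel1, Saa3, Scg2, Stra6, C3 and Rtn4rl2 on the lower side. The 4 genes 2-fold apart in opposite directions were Gm23706, Mir7054, Mir6907 and Gm24188, small RNA genes of at most 6 reads in a library, named after their values were seen. Across genes, which are not independent replicates, the log2 ratios had Pearson's r of 0.985 and Spearman's rho of 0.978. Both comparisons use the 1 WT library, and 3 simulated unchanged libraries gave r of 0.497 with counting noise alone and 0.502 with a spread of 0.4 between libraries. The covariance was 1.497, against 0.016 and 0.306 in those simulations, which gave 26.6 and 816 shared genes. The simulations gave all 3 libraries the same spread, so they do not cover a WT library that alone lies apart. The WT library cannot be split, so part or all of the excess may come from it.

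The comparison of BEM with BM asks how the mutants differ. Barhl1 set them apart, at 0.0107 FPKM in BEM and 95.1 FPKM in BM, a log2 ratio of -7.55 with the pseudocount. Next to Barhl1, differences were smaller: Gstp2, a glutathione transferase, was 2.44-fold lower in BEM (1.86 to 3.22), with 169 reads in BM and 82 in BEM, and Plac9b was 2.23-fold higher (1.64 to 3.07), with 58 and 153 reads. Both belong to families or pairs of near-identical genes that can share reads. Gm15760, a pseudogene named after its values were seen, was 3.55-fold lower in BEM (2.37 to 5.44), with 99 reads in BM and 33 in BEM. The reads of Gstp2 and Gm15760 rest on a length other than the annotated one. Lst1, a leukocyte gene, was 1.78-fold higher with 29 and 61 reads. The pseudogene Rpl36a-ps3 had 21 reads in BM and 45 in BEM, and the other genes named for the size of their ratio were microRNA and small nucleolar RNA genes of at most 40 reads in either library.

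Of the 12875 measured genes 59 were at least 2-fold higher and 42 at least 2-fold lower in BEM, which is 0.784%, and the counting interval excluded 1 for 6 and 8 of them, of which 9 had the annotated length. Of the 100 such genes with whole reads, 97 had fewer than 100 reads in both libraries together. Log2 ratios lay within 0.5 of 0 for 97.5% of genes, against 48.8% for BM and WT, and their SD across genes was 0.216, against 1.23. Of the hair cell and otic genes, Myo7a stood at 9.79 FPKM in BM and 9.83 in BEM and Atoh1 at 236.5 and 240.9, while Eya4 was 1.26-fold lower in BEM (1.08 to 1.47). Of genes below 1 FPKM, Cdh23, a cadherin of hair bundle tip links, was 2.01-fold lower (1.13 to 3.69), with 34 reads in BM and 20 in BEM. Also below 1 FPKM, Ptprq was 1.502-fold lower (1.08 to 2.10), with 85 and 67 reads, and Otog 2.11-fold lower (1.06 to 4.40), with 25 and 14 reads. Eya4, Cdh23, Ptprq and Otog were named by a rule that required the interval to exclude 1. That held for 10.8% of measured genes with whole reads. From the hair bundle list the rule also named Rdx, 1.06-fold higher in BEM (1.01 to 1.11), and Triobp, 1.08-fold lower (1.01 to 1.15). Retinoic acid genes had a median log2 ratio of -0.059 and proliferation genes of 0.041, and 0 of the 12 and 22 measured genes were 2-fold apart. Mesenchyme genes had a median of -0.009, signalling targets of 0.002 and Hox genes of -0.011, with Hoxa3 1.41-fold and Hoxd13 1.33-fold lower in BEM. Ribosomal protein genes were slightly higher, with a median of 0.061 above each random list, as for Rps29 (1.15-fold). The authors' deposited table marked 1 gene as significant for BEM against BM, Barhl1, with a log2 ratio of -13.11 and an FDR of 9.81e-11. The Barhl1 values were not whole reads. That FDR was 112500 times its p-value, more than the 47729 lines deposited for this comparison allow, so it is given with caution.

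**Figure D3:**
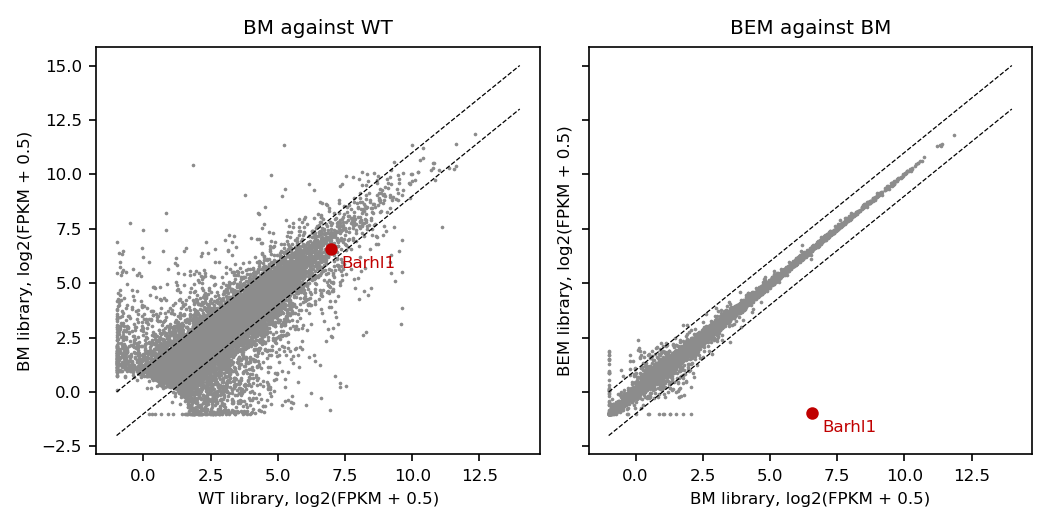
Expression of each measured gene in BM against WT (left) and BEM against BM (right), as log2(FPKM + 0.5) on both axes, with dashed lines at 2-fold and Barhl1 in red. On the left 3326 genes lie outside the lines and on the right 101, with Barhl1 far below the others at 0.0107 FPKM in BEM.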

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

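All the tests in this part were chosen after the result was seen. In the authors' deposited tables for BEM against WT and BM, Barhl1 had the smallest p-value of the genes analysed. Its FDR was 144414 times its p-value against WT and 112500 times against BM. For the gene with the smallest p-value the Benjamini-Hochberg adjustment allows this quotient to be at most the number of tests, and each deposited table has 47729 lines. Other genes of the BEM against WT table implied, from their FDR, p-value and rank, a median of 16214 tests and at most 16326 in the authors' deposited table. In the authors' deposited table for BM against WT the quotient of the first gene, Ecel1, was 8029, below the median of 16008 tests implied by the other genes there. What drew attention is the signal of Barhl1 in the p and FDR columns, which the ratios and the counts of genes 2-fold apart above do not use. The authors' own FDR values and numbers of significant genes given above do rest on these columns.

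The Barhl1 and Atoh1 values were the only ones among the 12875 measured genes that whole reads could not explain, with Lcn2 (0.0520, 0.114 and 0.0480 FPKM in WT, BM and BEM) as the only further gene among those of lower expression. Another gene length does not account for this, since 0 of the lengths up to 199999 bases gave whole reads in the 3 libraries, and fractional counting of reads shared with similar genes is argued against because 0 of 75 ribosomal protein genes, which have many near-identical copies, lacked whole reads. A candidate explanation is that the Barhl1 values were made in another way than the rest of the table, since in the authors' deposited table for BEM against WT the Barhl1 log2 ratio of -13.52 equals that of its FPKM, while the ratios of 6 other genes with a comparably low value in 1 library were shrunk by at least 1.62 on the log2 scale. How the values were made stays open, most of all for Atoh1, which is high in each library and so gives no such check, and the biological explanation that Barhl1 itself is lost in BEM was not tested, since it has 1 library and no other measurement here.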

How the results depend on the processing

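The tests with TMM scaling, with a pseudocount of 0.05 and without the genes lacking whole reads were chosen after the result was seen. Of 40 alternative values for the 4 main counts, 25 stayed within 1.5 times the count reported. The 15 others follow, and their causes were not tested beyond the construction of each setting. With a mean of at least 10 FPKM, which measures fewer genes, 1086 genes were 2-fold apart for BM against WT, 1086 for BEM against WT and 3 for BEM against BM (Gm25047, Gstp2 and Barhl1), and 1049 were shared. A pseudocount of 5 gave 1351, 1370 and 1, with 1301 shared, and a 4-fold threshold gave 1246, 1252 and 17. For BEM against BM alone, the count was 369 with no filter, 193 with a pseudocount of 0.05, 26 by the ratio in the authors' deposited table, and 1 (Gm15760) where the interval had to exclude ratios under 2. Gm25047 and Gm15760 were named after their values were seen. With no filter, 5 list medians changed sign against WT, to -0.156 (BM) and -0.144 (BEM) for neurons, -0.054 and -0.071 for cardiac and skeletal muscle, 0.015 and 0.051 for Hox genes, 0.567 and 0.577 for neural crest, and -0.027 (BM only) for the hair cell synapse list. Also with no filter, medians moved to -0.181 and -0.106 for endoderm, and 0.006 for muscle in BEM against BM. A pseudocount of 5 moved endoderm to -1.35 in both, proliferation to 0.67 and 0.66, signalling targets to -1.27 and -1.24, and muscle in BEM against BM to 0.012. A pseudocount of 0.05 moved endoderm to -6.21 and -6.99 (-0.517 for BEM against BM), neural crest in BEM to -1.26 and the synapse list in BEM against BM to 0.077. Upper quartile scaling moved ribosomal genes to 0.241 and 0.288, and in BM against WT it changed the sign of medians near 0, to 0.035 for the hair bundle, 0.069 for supporting cells, 0.116 for p53 targets and 0.121 for sex-linked genes. In all, 485 values of list medians stayed within the bootstrap interval of the main median, found by redrawing the list's members with replacement. Of these, 34 changed sign, from medians between -0.109 and 0.201. The farthest was -0.659, from 0.001, for supporting cells in BEM against WT with a mean of at least 10 FPKM. Of the values for named genes 2-fold apart, 721 moved by more than counting error, 444 did not, and 0 changed sign. Scaling by total reads alone is the setting already used, so it was not run again, and filters do not alter the ratio of a single gene. Genes 2-fold apart between BEM and BM had a median of 7 reads in both libraries together, so depth limits the precision of their ratios. No paired analysis was possible because each line had 1 library.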

Other observations

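The tests in this part were chosen only after the result was seen, except the test of genetic background, which was written before its result but after a few pseudogenes had been seen. Macrophage genes were examined further with 27 symbols chosen after the values of several had been seen, of which 3 also stand in the endothelium and blood list. Of the 25 measured, 23 were at least 2-fold higher in BM and 23 in BEM, with median log2 ratios of 4.34 and 4.28, and 6 were at 1 FPKM or more in WT. The most abundant were Lyz2 (3.08, 1380 and 1409 FPKM in WT, BM and BEM), C1qa (0, 119.6 and 126.9 FPKM), Cd68 (9.23, 116.7 and 118.0 FPKM) and Ctss (0.0342, 81.9 and 84.8 FPKM). The macrophage transcription factor gene Spi1 had 0 reads in WT and 523 in BM, and Adgre1, which encodes F4/80, had 3 and 1641 reads. Among acute-phase genes, which were picked after their values were seen and form no fixed list, Hp stood at 21.9, 0.0370 and 0 FPKM, Cp at 37.6, 0.244 and 0.189 FPKM, Lbp at 40.6, 0.288 and 0.1999 FPKM, and Steap4 at 34.7, 0.158 and 0.253 FPKM, while Lcn2, whose values were not whole reads, was not lower in BM, at 0.0520, 0.114 and 0.0480 FPKM.

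Xist, the RNA that silences an X chromosome in female cells, had 9 reads in WT, 6698 in BM and 7894 in BEM. Of the Y-linked genes, Ddx3y was 1.34-fold higher in BM than in WT (1.23 to 1.47) and Eif2s3y 1.39-fold lower (1.27 to 1.52). Processed pseudogenes that went from under 3 reads in WT to at least 100 in BM were Gm13736, Gm8615, Rps24-ps3, Rps2-ps13 and Gm15772, the last with 2 reads in WT, 1934 in BM and 2433 in BEM.

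BM and BEM lay close together outside Barhl1. Too little depth is argued against as the reason, because the median gene's counting interval had a half-width of 0.166 on the log2 scale. A single library read 2 times over is argued against as well, since 12% (11.3% to 12.7%) of the 8232 genes with at least 100 reads lay past the 5% point of counting noise. That both libraries could come from 1 RNA or culture stays open: the median squared difference was 1.55 times that of counting noise, just past the bound of 1.5 set for it, against 104 times for BM and WT, but the noise of library preparation has no measure here. The closeness may also be biological, with BM and BEM acting alike, which was not tested.

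WT stood apart from both mutants. Macrophages in the mutant cultures, though a candidate source of Lyz2 and C1qa, are argued against as the whole cause, since mesenchyme genes had a median log2 ratio of 1.56 in BM against WT. A different genetic background of WT cannot be told apart from other causes. Between under 3 and at least 100 reads, 5 of 255 pseudogenes switched, all of them higher in BM than in WT. That share was 0.688 times (0.224 to 1.58) that of coding genes matched on reads, an interval that includes 1. The prediction had more switches than in coding genes, and in both directions, but 0 went the other way. In BEM 6 pseudogenes switched upwards and 0 downwards, a share 0.843 times that of matched coding genes. Female cells mixed into the mutant cultures cannot be told apart either. Xist was detected in the mutants, as this explanation predicts, with 6698 reads in BM and 7894 in BEM against 9 in WT. It also predicts all 4 Y-linked genes below a ratio of 1 in BM against WT. Of the 4, 3 lay below 1, with ratios from 0.721 to 1.34 that follow no common share. The genotype and any other difference between single cultures are confounded, and the genotype stays an untested explanation.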
